A study of Mus musculus with 18 samples.

How the data were processed

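The data were RNA-seq values from the arcuate nucleus of female mice, a hypothalamic region that controls reproduction and feeding. Per the labels, wild-type (WT), ERα knockout (ERKO) and ERα KIKO mice were ovariectomized and given oil or estradiol benzoate (E2), 250 ng on day 5 and 1500 ng on day 6 after surgery. Tissue was collected 24 h after the second injection, following a 1 h fast. The 3 genotypes and 2 treatments made 6 groups of 3 libraries, 18 in all. The labels do not say how the KIKO and ERKO alleles were built or whether each library came from a single animal, so replicates are counted as libraries.

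The authors deposited 1 gene table per library, with values in FPKM (fragments per kilobase of transcript, scaled to the total fragments of the library). Lower and upper confidence bounds, also in FPKM, and a status for each gene stood beside them. The authors' notes name TopHat2 2.0, Cuffdiff and the genome build mm10, and do not name the annotation. The gene starts did not lie on that build: of 20590 symbols found on the same chromosome of the RefSeq annotation of GRCm38, 990 (4.81%) started within 1000 bases of the listed start. Chromosomes are therefore given without positions. All 18 tables listed the same 23699 entries under 23235 symbols, and entries sharing a symbol were summed. Symbols were matched to the annotation directly or by an older name for 98.0% of the 23235.

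Totals of fragments were worked out from the width of the confidence bounds. Where the bounds were symmetric, the fragment number they imply was whole, within a tolerance of 0.02, for 77.6% to 80.6% of the genes examined per library. The implied totals ran from 12770000 to 26020000 fragments, and the relative depth over 2265 genes from 0.728 to 1.50. These totals are inferred and were not used in the tests.

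Each gene was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). A single fit held all 18 libraries and 6 group means (12 residual degrees of freedom), with moderated variances that followed mean expression and were robust to extreme genes. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Genes with a mean of at least 0.5 FPKM were tested, without microRNA, small nucleolar and small nuclear RNA genes, which left 14773. The 10 comparisons were E2 against oil in each genotype, KIKO and ERKO against WT under each treatment, and the 3 differences between genotypes in the E2 response. Log2 changes are on this scale, with the standard error of the fit. The added 1 makes changes of genes with low FPKM smaller than the ratio of their means. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

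Before the data were examined, the tests, 15 gene lists, 14 marker lists of cell types and neighbouring tissues, and the rule for naming genes were fixed. The lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the 29 lists. The rule named Esr1, up to 8 of the largest rises and falls past the threshold, without overlap where 2 groups were compared and without clone-named genes, and up to 4 members of each list past the threshold. It allowed the arcuate panel in E2 comparisons, and added up to 10 genes with the smallest p where fewer than 5 passed. Pcsk1 was named outside this rule, as the remaining member of a list with 5 genes past the threshold, after its values were seen. Some genes that the rule names are not reported here, and the counts include them.

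On simulated data with the spread of these libraries, 100 genes changed by 1 on the log2 scale were recovered at 76% and 100 genes changed by 2 at 95%, with 8 unchanged genes called. The changed genes had a mean log2(FPKM + 1) above 1, and each gene varied on its own with the same spread in all groups. Recovery at lower expression was not simulated. Alternatives to the pseudocount, the filter, the scaling, the variance model, the libraries fitted and a replicate block were tried, each library of the groups compared was left out in turn, and further alternatives were chosen after seeing the data. A correction for transcript length and GC content removed a smooth trend (lowess span 0.3) from each library. The alternatives for count data were not run since the values are FPKM.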

Results

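Gene expression in the arcuate nucleus was measured by sequencing of total RNA from ovariectomized female mice of 3 genotypes, each treated with oil or E2. Every one of the 6 groups held 3 libraries (n = 3 throughout). WT mice carry intact ERα, the estrogen receptor encoded by Esr1, and ERKO mice lack it. KIKO mice, as the name is generally used, carry a knocked-in ERα that cannot bind estrogen response elements (EREs) over a null allele. The series title frames the question as which E2 responses need binding to these elements. The implied depth ran from 12770000 fragments in ERKO E2 3 to 26020000 in KIKO oil 2. Across tested genes, ERKO E2 3 correlated with the other libraries at 0.914 to 0.947, against 0.956 to 0.990 among the other 17. Values are FPKM as mean ± SD, or log2 change ± SE of the limma fit, and adjusted p values are from limma.

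**Figure D1:**
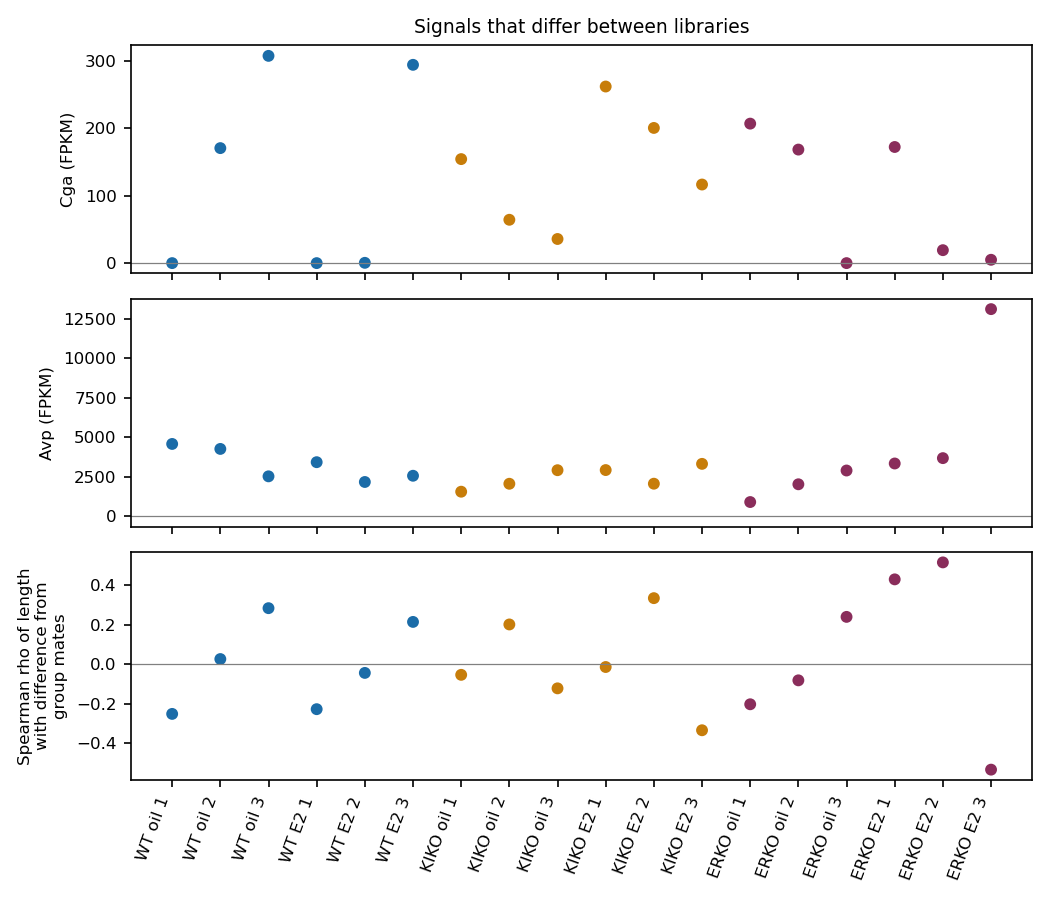
Levels per library (points, n = 18) of Cga (pituitary hormone subunit, FPKM), Avp (vasopressin, FPKM) and the Spearman rho across genes of transcript length with the difference from the other libraries of the group. ERKO E2 3 has the highest Avp, 13107 FPKM, and the lowest rho, −0.534.

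Esr1 itself, on chromosome 10, was highest in WT, at 8.05 ± 3.39 FPKM in oil and 4.86 ± 1.26 after E2. KIKO libraries held 3.65 ± 0.637 and 3.27 ± 0.552 FPKM, and ERKO libraries 2.09 ± 0.417 and 1.49 ± 1.13 FPKM. Esr1 was lower in ERKO oil than in WT oil (log2 change −1.49 ± 0.32, adjusted p = 0.0367). This call was lost in 8 of 21 alternatives. The other Esr1 differences did not pass: −0.91 ± 0.32 for KIKO oil against WT oil (adjusted p = 0.329), −1.34 ± 0.32 for ERKO E2 against WT E2 (0.0569) and −0.44 ± 0.32 for KIKO E2 against WT E2 (0.762). The first 2 of these passed without ERKO E2 3 in the fit, at −0.91 and −0.88 (adjusted p = 0.0473 and 0.0373), and over the alternatives their adjusted p ran from 0.0311 to 0.670 and from 0.0167 to 0.830. FPKM cannot tell an intact transcript from an altered one. Of 87 tested genes within 20 Mb of Esr1, 0 passed the threshold in KIKO oil and ERKO oil against WT oil or in KIKO E2 and ERKO E2 against WT E2 (two-sided Fisher exact p = 1, 0.639, 1 and 0.632). The numbers that passed were 1, 19, 1 and 2 without ERKO E2 3 in the fit, with Syne1 in each comparison (two-sided Fisher exact p = 1, 1, 0.268 and 0.0334, and an odds ratio of 0.244 for the last). With all libraries in the fit, 2, 204, 133 and 183 of 14068 genes on other chromosomes passed. At such low shares 0 of 87 is likely in any case, and it does not show that genes near Esr1 are unaffected.

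**Figure D2:**
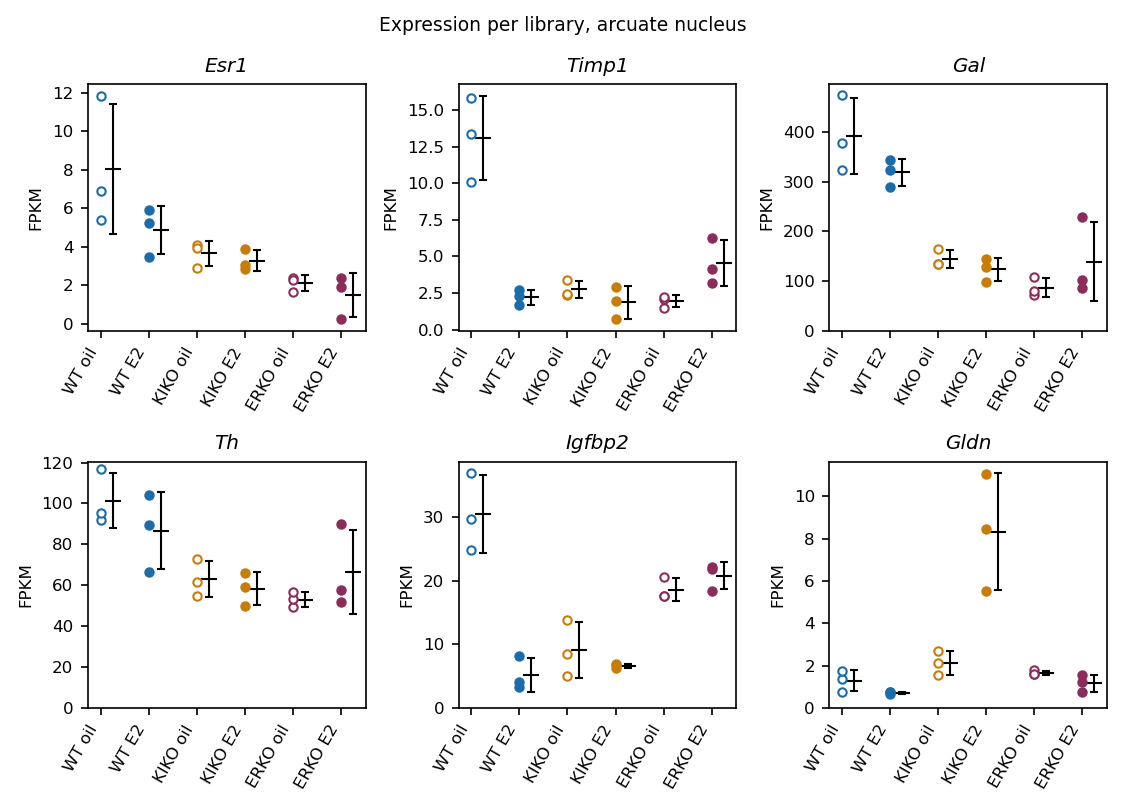
FPKM per library (points, open for oil and filled for E2; blue WT, orange KIKO, purple ERKO) with group mean and SD (bars, n = 3) for 6 genes. Timp1 and Gal are highest in WT oil, at 13.1 and 392 FPKM, and Gldn is highest in KIKO E2, at 8.34 FPKM.

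In WT mice, expression of the peptides of the KNDy neurons fell after E2. These neurons make kisspeptin, neurokinin B and dynorphin and set the pulses of gonadotropin-releasing hormone. Kiss1 (kisspeptin) fell from 433 ± 81.2 to 38.0 ± 18.9 FPKM (log2 change −3.58 ± 0.32, adjusted p = 1.28e-05). Tacr3, the neurokinin B receptor, fell from 13.2 ± 4.80 to 2.60 ± 0.554 FPKM, and Tac2, which encodes neurokinin B, from 1256 ± 172. to 542 ± 80.6 FPKM. Pdyn, the dynorphin precursor, fell from 171 ± 34.3 to 77.8 ± 16.8 FPKM. At the same time Greb1, an ERα cofactor, rose from 0.475 ± 0.222 to 5.44 ± 0.768 FPKM and Pgr, the progesterone receptor, from 4.44 ± 1.09 to 15.8 ± 2.11 FPKM.

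Of 14773 genes, 116 passed the threshold in WT, 89 rising and 27 falling, and 52 changed at least 2-fold. In each of the 116 the 3 E2 libraries lay apart from the 3 oil libraries. Among all genes 15.8% were apart in this way, against 10% by chance. Rln3, the neuropeptide relaxin-3, was listed at 0 in all 3 oil libraries and at 11.4, 16.4 and 9.47 FPKM in the E2 libraries (adjusted p = 6.20e-07). Further large rises were those of Aqp5, a water channel (log2 change 3.30 ± 0.23), Fam151a (2.30 ± 0.17), Mad2l1, a spindle checkpoint protein (2.16 ± 0.18), Col24a1, a collagen (2.06 ± 0.14), Phf21b (1.84 ± 0.19) and Smoc2, a matrix protein (1.81 ± 0.29). Their adjusted p values ran from 6.20e-07 for Col24a1 to 0.00423 for Smoc2.

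Igfbp2, which binds insulin-like growth factors, fell by 2.41 ± 0.28 on the log2 scale and Timp1, an inhibitor of metalloproteinases, by 2.12 ± 0.27. The falls of Lhfpl1 (−1.61 ± 0.16), Procr, the protein C receptor (−1.60 ± 0.24), and Nxph3, a neurexin ligand (−1.44 ± 0.21), also passed. Vgf, a precursor of secretory peptides, dropped from 664 ± 67.8 to 245 ± 57.5 FPKM and Bdnf, a neurotrophin that restrains feeding, from 4.69 ± 0.996 to 1.36 ± 0.381 FPKM. The largest adjusted p among these 7 genes was that of Bdnf, 0.00287.

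Of 20 measured members of the KNDy and reproductive peptide list, 0 rose and 5 fell (1 and 6 adjusted over the list alone). The members that fell were Kiss1, Tacr3, Tac2, Pdyn and Pcsk1, a prohormone convertase (−1.06 ± 0.23, adjusted p = 0.0377). As a set the list fell with a preset correlation (adjusted p = 0.000480), while the adjusted p was 0.165 with an estimated correlation. Among 23 estrogen-responsive genes 4 rose and 0 fell, both over all genes and adjusted over the list alone. These 4 were Greb1, Pgr, the oxytocin receptor Oxtr (1.37 ± 0.21) and the cholecystokinin receptor Cckar (0.76 ± 0.16). The set test did not pass (adjusted p = 0.0720 preset, 0.362 with an estimated correlation), and the median member change was −0.01 where the mean was 0.20.

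Of 22 dopamine and prolactin genes 4 rose and 0 fell (6 and 3 adjusted over the list alone). Nr4a2, a nuclear receptor of dopamine neurons, rose from 2.03 ± 0.632 to 8.25 ± 0.759 FPKM. Socs2 and Stat5a, in growth hormone and prolactin signalling, rose by 0.99 ± 0.17 and 0.89 ± 0.19, and the peptide neurotensin (Nts) by 1.03 ± 0.22. The set test gave an adjusted p of 0.348. Of the 14 arcuate panel genes 2 rose and 3 fell (2 and 5 over the list alone; adjusted p = 0.321). In the energy balance list, 1 of 26 genes rose and 1 fell (1 and 2 over the list alone): Ghsr, the ghrelin receptor, from 3.95 ± 2.06 to 12.7 ± 2.26 FPKM (adjusted p = 0.0409), and Bdnf. The feeding peptides did not pass: Agrp 0.67 ± 0.33, Npy 0.14 ± 0.28, Pomc −0.63 ± 0.25 and Cartpt −0.94 ± 0.29. Cartpt passed in 5 of 21 alternatives, with adjusted p from 0.00914 to 0.485, and Pomc in 2, with 0.0459 to 0.675. Ghrh (0.46 ± 0.26), Sst (−0.20 ± 0.21), Th (−0.24 ± 0.20), Gal (−0.28 ± 0.28) and Prlr (−0.01 ± 0.18) did not pass either, with adjusted p from 0.602 to 0.996, although Ghrh passed in 1 alternative.

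Single members of channel, transmission and cell type lists also passed. Grik1, a kainate receptor subunit, rose by 0.80 ± 0.14 and Kcnk2, a leak potassium channel, by 0.48 ± 0.10. Olig2, a regulator of the oligodendrocyte lineage, fell by 0.63 ± 0.10, the neurofilament Nefm by 0.73 ± 0.14 and the heat shock gene Hspa1a by 0.79 ± 0.17. No member of the interferon and MHC class I list passed among 22, and its median was −0.49 (adjusted p = 2.16e-07 preset, 0.362 with an estimated correlation). The immediate early list (median −0.20) and the neuron (−0.10), oligodendrocyte (−0.32), oligodendrocyte precursor (−0.16) and pituitary (−0.80) marker lists were lower at the preset correlation, with adjusted p of 0.0104, 0.0487, 6.60e-05, 0.0257 and 0.0487. With an estimated correlation none of the 7 lists that passed in WT did so, with adjusted p of 0.362, 0.362, 0.362, 0.340 and 0.679 for these 5. The list counts were 0 rising and 0 falling for immediate early genes (2 and 5 over the list alone) and 0 and 1 for neuron and precursor markers (0 and 1 alone). The other lists did not pass, with adjusted p from 0.0620 to 0.951. Cga, a pituitary hormone subunit, was at 0, 170 and 307 FPKM in the WT oil libraries and at 0, 0.424 and 294 FPKM in the WT E2 libraries.

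Without ERKO E2 3 in the fit, a library that correlated less with the rest, 397 genes passed in WT, and leaving out WT E2 1, 2 or 3 gave 71, 72 and 77, and only the WT groups in the fit 71. Of 34 named genes past the threshold, 22 kept their call in each of 6 fits without 1 WT library, while Ghsr, Nts, Socs2, Stat5a, Grik1, Cckar, Kcnk2, Nefm, Hspa1a, Pdyn, Tac2 and Pcsk1 lost it in at least 1 fit. Pdyn also lost it with no filter on low values, quantile normalization, a replicate block and the length and GC correction, with changes from −1.13 to −1.08, and Smoc2 with only the WT groups in the fit.

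**Figure D3:**
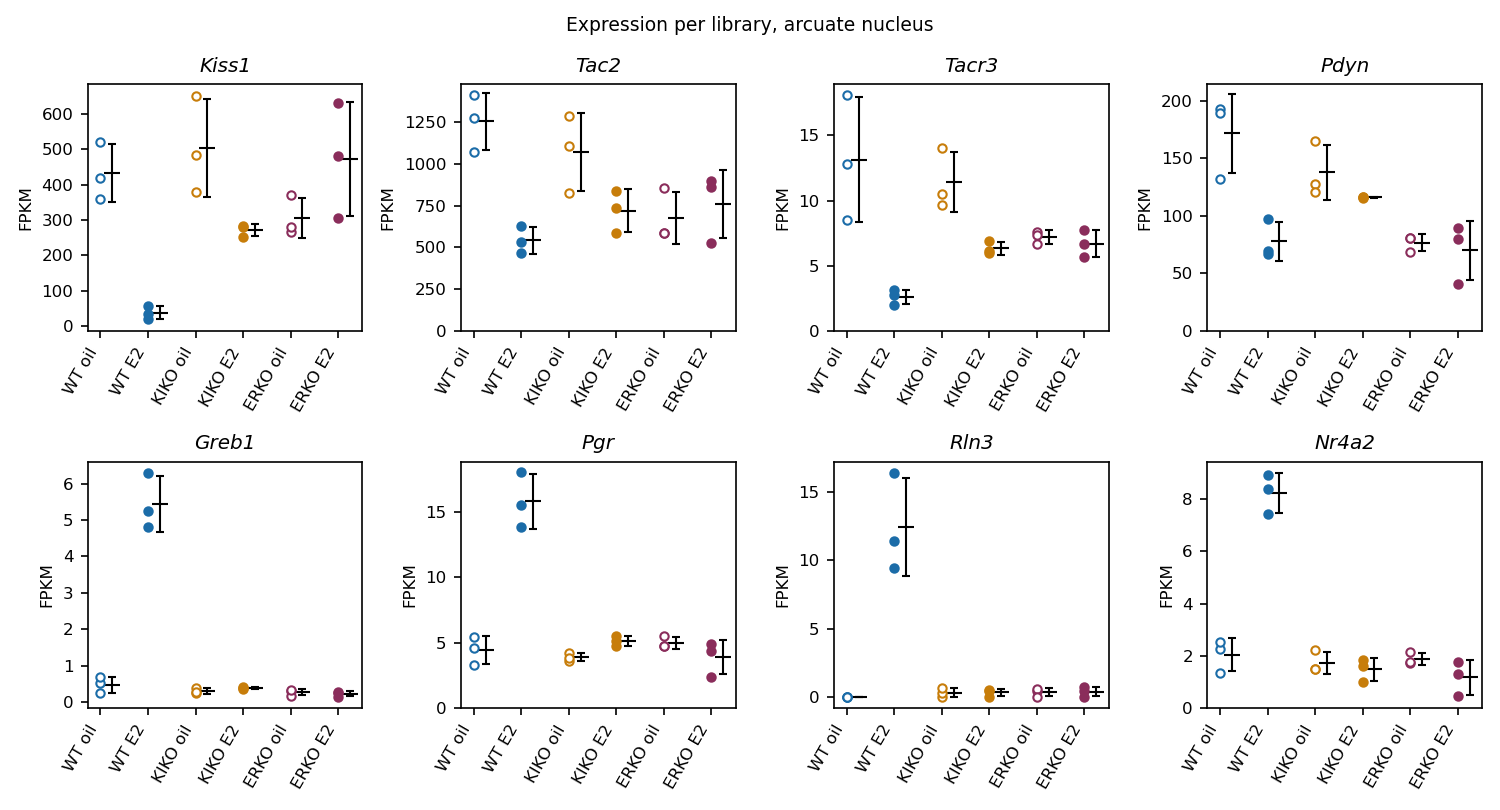
FPKM per library (points, open for oil and filled for E2; blue WT, orange KIKO, purple ERKO) with group mean and SD (bars, n = 3) for 8 genes. Kiss1 is at 433 FPKM in WT oil and 38.0 FPKM in WT E2, and Greb1, Pgr, Rln3 and Nr4a2 are highest in WT E2.

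In KIKO mice, 1 gene passed after E2. Gldn, which encodes gliomedin and belongs to the ventromedial nucleus marker list, rose from 2.12 ± 0.570 to 8.34 ± 2.78 FPKM (log2 change 1.55 ± 0.22, adjusted p = 0.0441), with all 3 E2 libraries above the 3 oil libraries. Kiss1 stood at 504 ± 138 FPKM in oil and 272 ± 16.1 FPKM after E2 and did not pass (−0.85 ± 0.32, adjusted p = 1). Its 3 E2 libraries lay below its 3 oil libraries, with an unadjusted limma p of 0.0159, so an absence of response is not shown. Groups without overlap were found for 7.41% of all genes in KIKO, against 10% by chance. Tac2 (−0.57 ± 0.24), Pdyn (−0.23 ± 0.24), Pgr (0.32 ± 0.19) and Greb1 (0.08 ± 0.13) did not pass either.

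The 9 genes with the smallest p after Gldn without overlap between KIKO groups were 6330403A02Rik (0.88 ± 0.15), Tmem35 (−0.60 ± 0.11), Sox3, a neural transcription factor (−0.75 ± 0.15), Cthrc1 (−0.51 ± 0.12), Bdnf (−0.76 ± 0.19), Rgs4, a brake on G protein signalling (−0.41 ± 0.11), Col5a1 (0.64 ± 0.16), 6330527O06Rik (0.99 ± 0.27) and Glb1l2 (0.51 ± 0.14). None passed, with adjusted p from 0.257 upwards, while 6330403A02Rik, Tmem35 and Sox3 passed with library weights. The remaining panel values lay between −0.29 ± 0.29 for Cartpt and −0.03 ± 0.25 for Pomc, with Agrp, Npy, Th, Prlr, Ghrh, Gal and Sst between them. Esr1 stood at −0.12 ± 0.32. At an unadjusted p under 0.05, limma gave 140 of 14773 genes. This share is below 0.05, so the count shows no excess over chance. Among lists, 20 KNDy genes had a median of −0.15 (adjusted p = 0.000129 preset, 0.0734 with an estimated correlation) and 14 arcuate panel genes a median of −0.20 (0.00187 and 0.181), with 0 members past the threshold in either. Adjusted over the list alone, 1 KNDy gene and 0 panel genes fell. Of the 8 lists past the preset threshold, 0 passed with an estimated correlation. The Gldn call was kept without KIKO E2 1 and lost without any of the other 5 KIKO libraries, where 0 genes passed.

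In ERKO mice, 0 genes passed after E2 in limma, with 1068 at an unadjusted p under 0.05 and a smallest adjusted p of 0.473. Kiss1 was at 305 ± 56.5 FPKM in oil and 472 ± 161 FPKM after E2 (0.58 ± 0.32), Pomc, which encodes melanocortin peptides, at 625 ± 34.1 and 1122 ± 490. FPKM (0.75 ± 0.25) and Cartpt at 361 ± 25.9 and 627 ± 338 FPKM (0.66 ± 0.29). ERKO E2 3 held 1646 FPKM of Pomc and 1009 FPKM of Cartpt, and without it the changes were 0.43 and 0.26, and that of Gal 0.13. Greb1 (−0.05 ± 0.13), Pgr (−0.33 ± 0.19), Tac2 (0.15 ± 0.24) and Esr1 (−0.43 ± 0.32) did not pass. Panel genes otherwise ran from −0.39 ± 0.18 for Prlr to 0.56 ± 0.28 for Gal. Th, Npy, Agrp, Ghrh, Sst and Pdyn lay between these values.

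The 10 genes with the smallest p without overlap in ERKO did not pass. They were Fos, an immediate early gene (−0.82 ± 0.17), Eny2 (−0.40 ± 0.10), Gm6644 (2.88 ± 0.79), Tob1 (−0.32 ± 0.09), BC051628 (−0.51 ± 0.15), the histone deacetylase Hdac9 (−0.55 ± 0.16), Sac3d1 (0.61 ± 0.18), the lysosomal regulator Tfeb (0.45 ± 0.13), the Notch target Hes5 (0.78 ± 0.23) and Pcdhb14 (−0.62 ± 0.18). Mitochondrial respiratory genes had a median of 0.34 and heat shock genes of 0.20 (adjusted p = 1.01e-07 and 1.05e-05 preset, 0.920 for both with an estimated correlation). The other 4 lists past the preset threshold, for calcium, HCN and TRP channels, GABA and glutamate, immediate early and clock genes, had the same adjusted p of 0.920 with an estimated correlation. Without ERKO E2 3, Fos passed (−1.06, adjusted p = 0.00308), and over all alternatives its adjusted p ran from 0.00177 to 0.742. That library held 13107 FPKM of the vasopressin gene Avp, against 3345 and 3684 FPKM in the other 2 ERKO E2 libraries.

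The differences between genotypes in the E2 response address which WT changes depended on genotype. Between KIKO and WT, 20 genes passed, 4 with a positive and 16 with a negative difference. The positive ones were Kiss1 (2.72 ± 0.45, adjusted p = 0.0190), Gldn (1.95 ± 0.31), the ephrin receptor Ephb3 (0.98 ± 0.15) and Syt12, a synaptotagmin (0.97 ± 0.15). Negative ones took in Rln3 (−3.70 ± 0.35), Aqp5 (−3.13 ± 0.32), Mad2l1 (−2.32 ± 0.26), Fam151a (−2.27 ± 0.24), Col24a1 (−2.05 ± 0.19), Greb1 (−2.05 ± 0.19, adjusted p = 8.71e-05), Nr4a2 (−1.76 ± 0.31) and Tnxb, a tenascin (−1.76 ± 0.24). The Pgr difference, −1.32 ± 0.26, did not pass (adjusted p = 0.0823), but it passed in 7 of 27 alternatives, with adjusted p from 0.00196 to 0.244. Other panel genes that did not pass ran from −0.70 ± 0.46 for Agrp to 0.90 ± 0.34 for Pdyn, with Cartpt, Tac2, Pomc, Th, Gal, Sst, Prlr, Npy and Ghrh between, and Esr1 stood at 0.47 ± 0.46. The Kiss1 difference kept its sign and lost its call (adjusted p up to 0.0712) without WT oil 1, WT E2 1, KIKO oil 1, KIKO E2 1, KIKO oil 2 or KIKO E2 3. Nr4a2 lost its call in 11 of 12 such fits, Gldn and Ephb3 in 3 each and Syt12 in 2. With a pseudocount of 0.1, Rln3, Fam151a, Col24a1, Gldn and Nr4a2 lost their call as well (adjusted p from 0.0519 to 0.190). Their differences were larger there, such as −6.87 for Rln3. The number of genes was 11 without WT E2 1, KIKO oil 1 or KIKO E2 1, 7 without KIKO oil 2, 12 without KIKO E2 3 and 42 without ERKO E2 3 in the fit.

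Between ERKO and WT, 41 genes passed, 14 positive and 27 negative. Positive differences were those of Kiss1 (4.16 ± 0.45, adjusted p = 0.000242), Timp1 (3.00 ± 0.38), Igfbp2 (2.56 ± 0.40), Nxph3 (1.89 ± 0.30), Procr (1.87 ± 0.34), Vgf (1.86 ± 0.23), Tacr3 (1.83 ± 0.29), Lhfpl1 (1.44 ± 0.23) and Olig2 (0.73 ± 0.14). Timp1, Procr, Vgf and Olig2 were also lower in ERKO oil than in WT oil (−2.24, −1.19, −1.16 and −0.53), so their differences hold a gap under oil. Kiss1, Igfbp2, Tacr3 and Nxph3 were higher in ERKO E2 than in WT E2 (3.66, 1.89, 1.10 and 0.98). Negative ones were those of Rln3 (−3.67 ± 0.35), Aqp5 (−3.23 ± 0.32), Mad2l1 (−2.35 ± 0.26), Fam151a (−2.33 ± 0.24), Greb1 (−2.18 ± 0.19), Phf21b (−2.13 ± 0.27), Col24a1 (−2.13 ± 0.19), Nr4a2 (−2.08 ± 0.31) and Pgr (−1.97 ± 0.26, adjusted p = 0.00183). Panel genes that did not pass ran from −0.38 ± 0.26 for Prlr to 1.61 ± 0.41 for Cartpt, with Pomc at 1.38 ± 0.35 and Tac2 at 1.36 ± 0.33 (adjusted p = 0.143 and 0.119). Pdyn, Gal, Sst, Th, Npy, Ghrh, Agrp and Esr1 (0.15 ± 0.46) lay between. Pdyn passed in 3 of 26 alternatives, Pomc in 2 and Cartpt and Tac2 in 1 each. Procr lost its call in 7 and Olig2 in 8 of 12 fits without 1 WT or ERKO library. The number of genes was 25, 27 and 27 without ERKO oil 1, 2 or 3, 74 without WT oil 3, 104 without ERKO E2 2 and 63 without ERKO E2 3.

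The lists were also tested for differences in response. For KIKO against WT, 1 KNDy gene was positive and 0 negative among 20 (2 and 0 over the list alone), with adjusted p of 0.0486 preset and 0.305 with an estimated correlation. Among 23 estrogen-responsive genes 0 were positive and 1 negative (0 and 3 over the list alone), with 0.0247 and 0.205. For ERKO against WT, 2 KNDy genes were positive and 0 negative (3 and 0 alone; adjusted p = 0.0210 and 0.478), and 0 and 2 estrogen-responsive genes (0 and 3 alone; 0.0993 and 0.542). The pituitary list had a median difference of 1.67 between KIKO and WT (0.00658 and 0.681).

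Across the 116 genes that passed in WT, the median change in the WT direction was 0.93 in WT, 0.06 in KIKO and −0.05 in ERKO. In KIKO 77 of the 116 had the same sign as in WT, and the median was at the 100th percentile of 10000 random sets matched on expression. In ERKO 46 had the same sign, at the 26.0th percentile. The random sets drew genes one by one in the main fit, so the percentiles do not measure the spread between libraries. Without 1 library, the share with the same sign in KIKO ran from 54.2% to 67.6% of the genes that then passed in WT. A remaining response in KIKO is therefore not shown by the percentile. Adjusted over these genes alone, the response was smaller than in WT for 108 genes in KIKO and 115 in ERKO. The genes were chosen on the WT change that enters these differences, which favours smaller responses elsewhere. Across all tested genes the Pearson correlation of responses was −0.0767 for WT with KIKO and −0.0833 for WT with ERKO, with Spearman rho of −0.000699 and −0.0979; genes are not independent replicates.

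**Figure D4:**
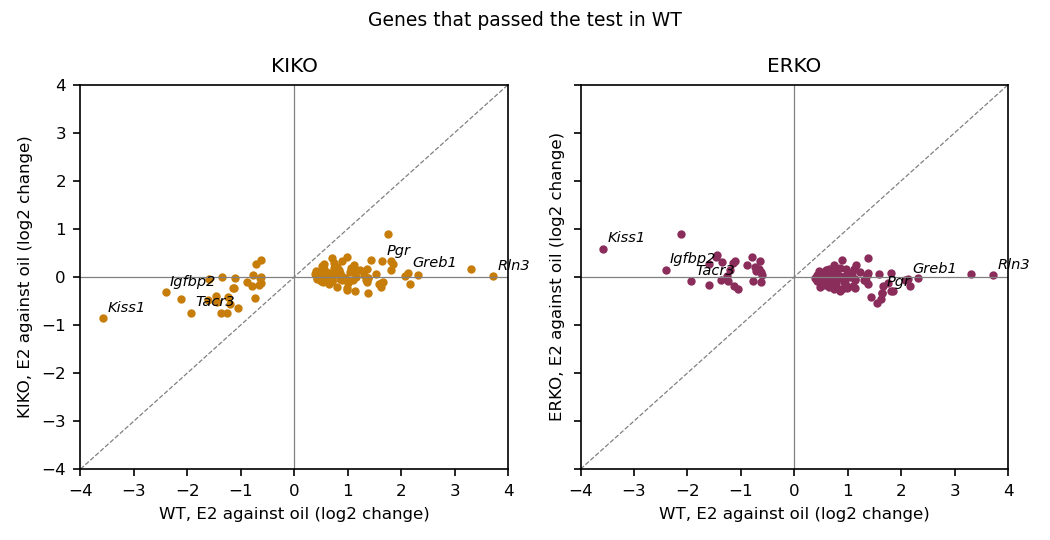
Log2 change with E2 in KIKO (orange, left) or ERKO (purple, right) against that in WT for the 116 genes that passed in WT, 1 point per gene, with the dashed line marking equal change. Kiss1 lies at −3.58 in WT, −0.85 in KIKO and 0.58 in ERKO.

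Between ERKO and KIKO, 0 response differences passed in limma (323 at an unadjusted p under 0.05, smallest adjusted p 0.286). The 323 are a share below 0.05 of the 14773 genes and show no excess over chance. Gldn had the smallest p (−1.87 ± 0.31), followed by 6330403A02Rik (−1.02 ± 0.22) and C1ql2 (1.12 ± 0.28), and the Kiss1 difference was 1.44 ± 0.45 (adjusted p = 0.746). Gm221 (−1.17 ± 0.31), Gm18756 (0.76 ± 0.21), Rab42-ps (−1.03 ± 0.28), Timp1 (1.34 ± 0.38), Cthrc1 (0.58 ± 0.17), 9030617O03Rik (−0.47 ± 0.14) and Vgf (0.81 ± 0.23) made up the 10 named by smallest p. The other panel genes and Esr1 ran from −0.65 ± 0.26 for Pgr to 0.96 ± 0.41 for Cartpt. Of the 7 lists past the preset threshold, 0 passed with an estimated correlation. The interval of a difference such as that of Kiss1 is wide, and a p above the threshold does not show that KIKO and ERKO respond alike.

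Under oil, without added estrogen, KIKO differed from WT in 2 genes, both lower in KIKO. Timp1 was at 13.1 ± 2.89 FPKM in WT oil and 2.74 ± 0.566 in KIKO oil (−1.90 ± 0.27) and Lhfpl1 at 2.73 ± 0.807 and 0.684 ± 0.235 FPKM (−1.14 ± 0.16), both with adjusted p = 0.0273. Both had also fallen with E2 in WT, but that comparison uses the same WT oil libraries, so the 2 results are not independent. The other 8 genes with the smallest p without overlap did not pass: Igfbp2 (−1.72 ± 0.28), Procr (−1.34 ± 0.24), the matrix protein Ecm1 (−1.08 ± 0.20), Pmepa1 (−0.77 ± 0.13), Elk3 (−0.66 ± 0.12), Ovgp1 (0.95 ± 0.16), Gm13845 (1.23 ± 0.22) and Tmem181c-ps (0.52 ± 0.10). Their adjusted p ran from 0.0816 to 0.0962, and all 8 passed without ERKO E2 3 in the fit. Among all genes 21.9% had groups without overlap, against 10% by chance.

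With an estimated correlation 3 lists passed in KIKO oil against WT oil, all lower and all with adjusted p = 0.0466. They were the estrogen-responsive genes (median −0.16), the dopamine and prolactin genes (−0.22) and the oligodendrocyte precursor markers (−0.23). In each 0 members passed over all genes, and adjusted over the list alone 0 rose and 3, 4 and 3 fell. The other 8 of 11 lists past the preset threshold lost it, with the arcuate panel (median −0.27) at an adjusted p of 0.0885. Without ERKO E2 3 in the fit 267 genes passed, without WT oil 1 or WT oil 3 the numbers were 4 and 8, without KIKO oil 3 it was 1, and without WT oil 2, KIKO oil 1 or KIKO oil 2 it was 0. Timp1 lost its call in each of 6 fits without 1 library of these groups and Lhfpl1 in 4.

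Between ERKO oil and WT oil, Gal, Th and Pdyn were lower in ERKO. Gal, which encodes galanin, stood at 392 ± 76.4 FPKM in WT and 86.6 ± 18.9 in ERKO (−2.17 ± 0.28, adjusted p = 0.00818). Th, the rate-limiting enzyme of dopamine synthesis, stood at 101 ± 13.5 and 52.9 ± 3.64 FPKM, and Pdyn at 171 ± 34.3 and 76.5 ± 7.38 FPKM. The log2 changes of Th and Pdyn were −0.92 ± 0.20 and −1.14 ± 0.24. Both lost their call with a replicate block, which left the changes as they were, and with the length and GC correction, at −0.80 and −0.95. Without 1 library of these groups Th lost its call in 5 of 6 fits, Pdyn in 6 and Gal in 1. Timp1 had the lowest p, at 13.1 ± 2.89 and 1.95 ± 0.392 FPKM (−2.24 ± 0.27, adjusted p = 0.00699).

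In total 212 genes passed, 111 higher and 101 lower in ERKO, and 21 by at least 2-fold. The number was 51 with the length and GC correction, 64 with a replicate block, 428 with the pars tuberalis covariate, 430 with quantile normalization, 1661 with only these groups in the fit and 2931 with library weights. Among all genes 39.3% had groups without overlap, against 10% by chance. Lower genes included Adh7, an alcohol dehydrogenase (−1.50 ± 0.26), Procr (−1.19 ± 0.24), Vgf (−1.16 ± 0.17), Hist2h3b, a histone (−1.13 ± 0.23), Cish, a brake on cytokine signalling (−0.98 ± 0.18), and Gfap, the astrocyte filament (−1.06 ± 0.20). Higher genes included Bub1b, a spindle checkpoint kinase (1.36 ± 0.29), Ovgp1 (1.01 ± 0.16), the noncoding RNA Snhg11 (0.95 ± 0.20), Agxt2l1 (0.94 ± 0.17), Ttc18 (0.79 ± 0.16), Cep70, a centrosome protein (0.75 ± 0.16), Odf2l (0.75 ± 0.15) and Pgbd1 (0.74 ± 0.16). The adjusted p of these genes ran up to 0.0367. With a replicate block Procr, Hist2h3b, Gfap, Bub1b, Snhg11, Ttc18 and Pgbd1 lost their call (adjusted p from 0.0523 to 0.0533).

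Among 9 oligodendrocyte precursor markers, Gpr17 (−1.06 ± 0.14), Olig2 (−0.53 ± 0.10) and Olig1 (−0.51 ± 0.12) were lower (0 rose and 5 fell over the list alone; adjusted p = 0.00594 preset, 0.196 with an estimated correlation). Of 22 dopamine and prolactin genes 3 fell (0 and 5 over the list alone; 0.000408 and 0.196) and of 14 panel genes 3 (0 and 5; 7.73e-06 and 0.141). Of 23 immediate early genes Fos was higher (0.73 ± 0.17) and Jun lower (−0.47 ± 0.11), with 1 and 2 over the list alone. The MHC class I gene H2-D1 (−0.56 ± 0.12) and Nefm (−0.62 ± 0.14) were lower as well. With the length and GC correction 16 of the 27 named genes lost their call, with Olig2 at −0.37, Olig1 at −0.26, H2-D1 at −0.32 and Hist2h3b at −0.58. Olig1, Fos, Jun, H2-D1 and Nefm lost theirs with a replicate block too (adjusted p from 0.0524 to 0.0755). Of the 12 lists past the preset threshold, 0 passed with an estimated correlation.

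Without ERKO E2 3 in the fit 3318 genes passed, and without ERKO oil 1, 2 or 3 or WT oil 1 or 2 the numbers were 6, 8, 1, 42 and 12. Of 27 named genes past the threshold, Timp1 alone kept its call in all 6 fits without 1 library of these groups.

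The comparisons under E2 address how each mutant differed from WT with the hormone present. They also hold any difference already present under oil. In KIKO E2 against WT E2, 140 genes passed, 30 higher and 110 lower. Kiss1 was higher in KIKO (2.92 ± 0.32, adjusted p = 0.000107), as were Gldn (2.40 ± 0.22), the synaptic gene Otof (1.17 ± 0.19), the ATP receptor P2rx5 (1.17 ± 0.19), Tacr3 (1.03 ± 0.21) and the Wnt modulator Rspo4 (0.93 ± 0.15). Lower genes included Rln3 (−3.35 ± 0.25), Aqp5 (−3.02 ± 0.23), Fam151a (−2.46 ± 0.17), Col24a1 (−2.35 ± 0.14), Mad2l1 (−2.32 ± 0.18), Col2a1, a cartilage collagen (−2.31 ± 0.21), Greb1 (−2.21 ± 0.13) and Lrrc38, a potassium channel subunit (−1.95 ± 0.14).

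The estrogen-responsive list was lower in KIKO E2 with both correlations (adjusted p = 1.83e-08 preset, 0.00137 estimated), with 0 of 23 higher and 5 lower (6 over the list alone). These 5 were Greb1, Pgr (−1.45 ± 0.19), Oxtr (−1.44 ± 0.21), Gal (−1.38 ± 0.28) and Cckar (−1.17 ± 0.16). The dopamine and prolactin list was also lower with both (4.34e-09 and 0.0207), with 1 of 22 higher and 6 lower (3 and 13 over the list alone), among them Nr4a2 (−1.91 ± 0.22), Socs2 (−1.74 ± 0.17), Nts (−1.41 ± 0.22) and Stat5a (−1.10 ± 0.19). Both lists were also lower in KIKO oil than in WT oil with an estimated correlation. Neither passed with it for the KIKO minus WT response, so a difference under oil enters these results. Gal did not pass with E2 in WT (−0.28 ± 0.28), and its KIKO minus WT response was 0.05 ± 0.40. Grik1 (−0.89 ± 0.14), Kcnk2 (−0.56 ± 0.10) and the immediate early gene Ier2 (−0.87 ± 0.15) were lower. Abcc8, a potassium channel regulator (0.71 ± 0.15), the glutamate receptor subunit Gria3 (0.55 ± 0.11) and the heat shock genes Hspa1b (1.06 ± 0.21) and Hspa1a (0.93 ± 0.17) were higher. The pituitary list had a median of 1.33 (0.000822 preset, 0.674 estimated). Without WT E2 1, 2 or 3 the number of genes was 81, 55 and 86, without KIKO E2 1, 2 or 3 it was 83, 61 and 81, and without ERKO E2 3 in the fit it was 596. Of 30 named genes past the threshold 9 lost their call without 1 library of these groups: Abcc8, Tacr3 and Gal in all 6 fits, Hspa1b in 5, Hspa1a and Gria3 in 4, Kcnk2 in 3, Ier2 in 2 and Stat5a in 1. The first 6 of these also lost it with the pars tuberalis covariate.

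In ERKO E2 against WT E2, 192 genes passed, 40 higher and 152 lower. Kiss1 was higher in ERKO (3.66 ± 0.32, adjusted p = 6.82e-06), with Igfbp2 (1.89 ± 0.28), Tacr3 (1.10 ± 0.21), Nxph3 (0.98 ± 0.21), the bombesin-like receptor Brs3 (0.93 ± 0.16), Sox3 (0.90 ± 0.15), the synaptic protein Lrrtm1 (0.89 ± 0.20) and Bdnf (0.83 ± 0.19). Rln3 (−3.30 ± 0.25), Aqp5 (−3.04 ± 0.23), Fam151a (−2.53 ± 0.17), Greb1 (−2.39 ± 0.13), Mad2l1 (−2.38 ± 0.18), Col24a1 (−2.36 ± 0.14), Col2a1 (−2.32 ± 0.21) and Nr4a2 (−2.14 ± 0.22) were lower.

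Estrogen-responsive genes were lower in ERKO E2 with both correlations (adjusted p = 4.13e-06 preset, 0.00499 estimated), with 0 of 23 higher and 6 lower (8 over the list alone), among them Pgr (−1.81 ± 0.19), Oxtr (−1.46 ± 0.21), Gal (−1.33 ± 0.28) and Cckar (−0.99 ± 0.16). For the ERKO minus WT response this list did not pass at either correlation. Gal was also lower in ERKO oil than in WT oil (−2.17 ± 0.28), and its response difference, 0.84 ± 0.40, did not pass. The dopamine and prolactin list had 0 of 22 higher and 6 lower (2 and 11 over the list alone; 8.43e-06 and 0.108), with Socs2 at −1.62 ± 0.17 and Stat5a at −1.35 ± 0.19. Ghsr (−1.61 ± 0.33), Nhlh2, a transcription factor of reproductive neurons (−0.72 ± 0.13), Ier2 (−0.74 ± 0.15) and Grik1 (−0.62 ± 0.14) were lower, and Hspa1a (0.78 ± 0.17) and the activity-dependent gene Npas4 (0.65 ± 0.13) were higher. Without ERKO E2 3, 1286 genes passed, and without WT E2 1, 2 or 3 the numbers were 116, 95 and 113. Of 29 named genes past the threshold 12 lost their call in at least 1 of 6 fits without 1 library of these groups, among them Gal and Ier2 in 5 and Lrrtm1, Bdnf, Hspa1a and Grik1 in 4. With only ERKO E2 and WT E2 in the fit 13 passed, Rln3, Aqp5, Fam151a, Greb1, Mad2l1, Col24a1 and Socs2 among them. The other named genes, Kiss1 included, lost their call there.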

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

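The tests weighed in this part were chosen before their results were seen, while the fits without ERKO E2 3, the length and GC correction and the pars tuberalis covariate were chosen after seeing the data. The results in the first paragraphs below are those whose E2 response differed between genotypes by a test of the difference itself, and 3 patterns follow.

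Between KIKO and WT the named genes with a different E2 response, as log2 differences, were Kiss1 (2.72), Gldn (1.95), Ephb3 (0.98), Syt12 (0.97), Tnxb (−1.76), Nr4a2 (−1.76), Greb1 (−2.05), Col24a1 (−2.05), Fam151a (−2.27), Mad2l1 (−2.32), Aqp5 (−3.13) and Rln3 (−3.70). Of 100 splits drawn from 200, 8, the real one included, gave as many genes as the real 20, with up to 51 in another split. The split with 51 kept KIKO E2 1, 2 and 3 together, so it held the real difference between KIKO E2 and WT E2. Chance is not excluded for this count, and splits that hold a genotype difference do not settle it either way. Kiss1 fell in WT and Greb1 and Rln3 rose there, and none of these 3 passed in KIKO.

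Between ERKO and WT they were Kiss1 (4.16), Timp1 (3.00), Igfbp2 (2.56), Nxph3 (1.89), Procr (1.87), Vgf (1.86), Tacr3 (1.83), Lhfpl1 (1.44), Olig2 (0.73), Pgr (−1.97), Nr4a2 (−2.08), Col24a1 (−2.13), Phf21b (−2.13), Greb1 (−2.18), Fam151a (−2.33), Mad2l1 (−2.35), Aqp5 (−3.23) and Rln3 (−3.67). Of these genes, Timp1, Procr, Vgf and Olig2 were also lower in ERKO oil than in WT oil, so their differences hold a gap under oil. The real split gave 41 genes, and 2 of 100 splits, the real one included, gave as many, with 64 in the other. That other split kept ERKO E2 1, 2 and 3 together, so it held the real difference between ERKO E2 and WT E2. Splits of this kind are not free of a genotype difference. The share is under 0.05, but it does not settle chance for the difference in response. For ERKO against KIKO the real count was 0 in limma. At an unadjusted p under 0.05 there were 323 genes, a share below 0.05 of those tested. With a real count of 0, each of 100 splits had to give as many, with up to 1 in another split, and the splits say nothing on chance.

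The Kiss1, Greb1 and Pgr response seen in WT was not called in KIKO or ERKO, although the Pgr difference between KIKO and WT did not pass (adjusted p = 0.0823). A length and GC bias as the whole cause is argued against, since 164 genes passed in WT after correction and 96 of the 116 were among them. Pars tuberalis tissue is argued against in the same way, with 133 genes passing beside the pituitary covariate, 101 of them shared. A wider spread among ERKO E2 libraries hiding the same response is argued against too. Without ERKO E2 3, 397 genes passed in WT, and their median change in the WT direction was −0.0545 in ERKO and 0.566 in WT. This set is larger than the 116, and its WT median is raised by the choice of genes on the WT change. A different mix of nuclei between WT dissections cannot be told apart, since the smallest adjusted p of these marker lists was 0.362 with an estimated correlation and a p above the threshold excludes nothing, and the genotype itself stays open as the biological explanation.

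Many genes, Gal, Th and Timp1 among them, differed between ERKO oil and WT oil. Without ERKO E2 3 in the fit, pars tuberalis tissue is argued against by the 3854 genes past the threshold with the covariate, 3315 of them shared with the 3318. Length and GC bias may account for part of the difference, as 1487 genes passed after correction, 1040 of them shared, which leaves it short of the whole. A difference in depth cannot be told apart: relative depth was 1.08 to 1.26 in the ERKO oil libraries and 0.778 to 0.954 in the WT oil libraries. The share past the threshold in genes of low expression was 0.394 times that in genes of high expression, which was set beforehand as evidence against it, but the added 1 lowers changes at low FPKM whatever the depth. A different mix of cell types cannot be told apart: the smallest adjusted p of the marker lists was 0.373 with an estimated correlation, which was set beforehand as evidence against it but excludes nothing, and precursor and oligodendrocyte markers passed at the preset correlation (0.0148 and 0.0182). Libraries carry serial codes that run by genotype, so genotype and any processing order cannot be told apart. This holds for each comparison of genotypes under a single treatment. The genotype stays open as the biological explanation, untested.

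ERKO E2 3 stood apart from the other 17 libraries. A loss of long transcripts, as with degraded RNA, may account for it: the Spearman rho across genes of transcript length with the difference from the other ERKO E2 libraries was −0.534, below the next lowest, −0.335 in KIKO E2 3. More tissue from the paraventricular, supraoptic and suprachiasmatic nuclei cannot be told apart, since Avp and Oxt were at 13107 and 7392 FPKM while the list of 11 markers had a corrected median of −0.60, with 5 above 0 and a range from −3.36 to 1.51. That median lay at the 0.3rd percentile of 10000 random lists, which was set beforehand as evidence against it, but members that go both ways decide nothing. No biological explanation was tested for a single library.

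For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 116 and 30 for WT E2 against oil, 1 and 0 for KIKO E2 against oil, 0 and 0 for ERKO E2 against oil in limma (1068 at an unadjusted p under 0.05), 2 and 1 for KIKO oil against WT oil, 212 and 0 for ERKO oil against WT oil, and 140 and 0 for KIKO E2 against WT E2. In ERKO E2 against WT E2 they were 192 and 1704, and the split with 1704, which put WT E2 3 with ERKO E2 1 and 2, points to a structure of the samples. Cga was at 294, 172 and 19.2 FPKM in these, and at 4.93, 0 and 0.424 FPKM in ERKO E2 3 and WT E2 1 and 2. The rho of transcript length was 0.214, 0.430 and 0.516 against −0.534, −0.228 and −0.0440. The 2 signals go together in this split and cannot be told apart. The WT split with 30 put WT oil 1 with WT E2 1 and 2, whose Cga was at 0, 0 and 0.424 FPKM.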

How the results depend on the processing

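ERKO E2 3 out of the fit, library weights, the length and GC correction, the pars tuberalis covariate and the removal of genes with a failed status were chosen after seeing the data. The Kiss1 fall and the Greb1 and Pgr rises in WT kept direction and call in every alternative run. For the changes below the cause was not tested, apart from the fewer libraries of a fit without some of them and the fewer or more genes tested under another filter. In comparisons that do not hold ERKO E2, leaving out ERKO E2 3 left the log2 changes as they were, such as −0.94 for Cartpt in WT. Counts moved there only through the variance estimates of the shared fit.

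With a pseudocount of 0.1, the genes past the threshold numbered 0 for KIKO E2 against oil, 0 for KIKO oil against WT oil and 9 for the KIKO minus WT response. Changes of sign there were Esr1 −0.24 in the ERKO minus WT response. With no filter on low values, the genes past the threshold numbered 3 for KIKO E2 against oil, 7 for KIKO oil against WT oil, 31 for the KIKO minus WT response and 2 for the ERKO minus KIKO response. With a mean of at least 2 FPKM, the genes past the threshold numbered 0 for KIKO oil against WT oil and 12 for the KIKO minus WT response. With quantile normalization, the genes past the threshold numbered 7 for KIKO oil against WT oil, 430 for ERKO oil against WT oil and 26 for the ERKO minus WT response. Signs changed there for Npy −0.082, Tac2 −0.19 and Greb1 0.092 in ERKO E2 against oil, and Npy −0.28 in the ERKO minus WT response, and Npy −0.053, Pdyn −0.078 and Greb1 0.026 in the ERKO minus KIKO response. With only the groups compared in the fit, the genes past the threshold numbered 71 for WT E2 against oil, 0 for KIKO E2 against oil, 10 for KIKO oil against WT oil, 1661 for ERKO oil against WT oil, 13 for ERKO E2 against WT E2 and 18 for the ERKO minus WT response. With a replicate block, the genes past the threshold numbered 0 for KIKO E2 against oil, 1 for KIKO oil against WT oil and 64 for ERKO oil against WT oil. With ERKO E2 3 out of the fit, the genes past the threshold numbered 397 for WT E2 against oil, 1 for ERKO E2 against oil, 267 for KIKO oil against WT oil, 3318 for ERKO oil against WT oil, 596 for KIKO E2 against WT E2, 1286 for ERKO E2 against WT E2, 42 for the KIKO minus WT response and 63 for the ERKO minus WT response. Reversed log2 values were Ghrh −0.030, Agrp −0.041, Pdyn 0.14 and Esr1 0.021 in ERKO E2 against oil, and Npy −0.12 in the ERKO minus WT response, and Agrp −0.011, Prlr 0.013 and Esr1 0.14 in the ERKO minus KIKO response. With library weights, the genes past the threshold numbered 209 for WT E2 against oil, 4 for KIKO E2 against oil, 1 for ERKO E2 against oil, 350 for KIKO oil against WT oil, 2931 for ERKO oil against WT oil, 1028 for KIKO E2 against WT E2, 1301 for ERKO E2 against WT E2, 59 for the KIKO minus WT response and 73 for the ERKO minus WT response. In sign, changes were Pomc 0.093 in KIKO E2 against oil, and Ghrh −0.037, Agrp −0.11, Npy −0.076, Greb1 0.020 and Pdyn 0.12 in ERKO E2 against oil, and Npy −0.29 in the ERKO minus WT response, and Prlr 0.042 and Esr1 0.18 in the ERKO minus KIKO response. With the length and GC correction, the genes past the threshold numbered 6 for KIKO oil against WT oil, 51 for ERKO oil against WT oil, 314 for ERKO E2 against WT E2, 38 for the KIKO minus WT response and 68 for the ERKO minus WT response. Sign changes were those of Tac2 −0.066 and Greb1 0.11 in ERKO E2 against oil, and Npy −0.15 in the ERKO minus WT response, and Pdyn −0.18 and Greb1 0.024 in the ERKO minus KIKO response. With that correction and ERKO E2 3 out of the fit, the genes past the threshold numbered 414 for WT E2 against oil, 1 for ERKO E2 against oil, 216 for KIKO oil against WT oil, 1487 for ERKO oil against WT oil, 735 for KIKO E2 against WT E2, 1329 for ERKO E2 against WT E2, 70 for the KIKO minus WT response and 93 for the ERKO minus WT response. Values of the other sign were Ghrh −0.084, Agrp −0.091, Npy −0.016, Tac2 −0.012, Pdyn 0.097 and Esr1 0.046 in ERKO E2 against oil, and Npy −0.18 in the ERKO minus WT response, and Agrp −0.087, Prlr 0.062 and Esr1 0.18 in the ERKO minus KIKO response. With the pars tuberalis covariate, the genes past the threshold numbered 0 for KIKO E2 against oil, 428 for ERKO oil against WT oil and 70 for the ERKO minus WT response. There, the sign changed for Prlr 0.072 in WT E2 against oil, and Pomc 0.024 in KIKO E2 against oil, and Sst 0.13 in the KIKO minus WT response, and Pdyn −0.018 in the ERKO minus KIKO response. Leaving out each library of the groups compared in turn gave 71 to 152 for WT E2 against oil, 0 to 1 for KIKO E2 against oil, 0 to 1 for ERKO E2 against oil, 0 to 8 for KIKO oil against WT oil, 1 to 287 for ERKO oil against WT oil, 55 to 86 for KIKO E2 against WT E2, 95 to 1286 for ERKO E2 against WT E2, 7 to 25 for the KIKO minus WT response, 25 to 104 for the ERKO minus WT response and 0 to 1 for the ERKO minus KIKO response. Values whose sign changed in WT E2 against oil were Prlr from −0.23 to 0.14. In the KIKO minus WT response they were Th from −0.048 to 0.27, Gal from −0.097 to 0.20, Sst from −0.15 to 0.11, Prlr from −0.33 to 0.041 and Npy from −0.55 to 0.0022. In the ERKO minus WT response they were Esr1 from −0.13 to 0.61, Npy from −0.12 to 0.30 and Ghrh from −0.49 to 0.21. In KIKO E2 against oil they were Pomc from −0.14 to 0.17, Agrp from −0.44 to 0.20 and Npy from −0.41 to 0.14. In the ERKO minus KIKO response they were Agrp from −0.011 to 0.75, Pdyn from −0.18 to 0.38, Prlr from −0.31 to 0.013 and Esr1 from −0.59 to 0.14. In ERKO E2 against oil they were Ghrh from −0.030 to 0.67, Agrp from −0.041 to 0.51, Pdyn from −0.41 to 0.14 and Esr1 from −0.71 to 0.021. With the length and GC correction, the number of lists past the threshold was 3 for WT E2 against oil and 4 for the ERKO minus WT response. With that correction without ERKO E2 3, the number of lists past the threshold was 3 for WT E2 against oil and 2 for the ERKO minus WT response. With an estimated correlation, the number of lists past the threshold was 0 for WT E2 against oil, 0 for KIKO E2 against oil, 0 for ERKO E2 against oil, 3 for KIKO oil against WT oil, 0 for ERKO oil against WT oil, 2 for KIKO E2 against WT E2, 1 for ERKO E2 against WT E2, 0 for the KIKO minus WT response, 0 for the ERKO minus WT response and 0 for the ERKO minus KIKO response. With ERKO E2 3 out of the fit, the number of lists past the threshold was 7 for ERKO E2 against WT E2, 5 for the KIKO minus WT response and 3 for the ERKO minus WT response. With ERKO E2 3 out of the fit, the odds ratio for genes near Esr1 in ERKO E2 against WT E2 was 0.244 (Fisher exact p = 0.0334), and the Pearson correlation of responses across genes was −0.197 for WT with ERKO and 0.0291 for KIKO with ERKO, where the sign changed from −0.0498. The median change of the WT genes stayed between 0.0122 and 0.0600 in KIKO and −0.0775 and −0.00394 in ERKO without 1 library.

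Of the values of named genes, 270 kept direction and call with median-of-ratios scaling and 3 lost the call; with plain variance moderation and with short RNA genes kept, all 273 kept both. Calls were lost for 12 with the pseudocount, 9 without a filter, 37 with only the groups compared, 31 with the block, 14 with quantile normalization, 2 with a mean of at least 2 FPKM, 23 with the length and GC correction, 3 with that correction without ERKO E2 3, 12 with the pars tuberalis covariate and 1 with library weights. Whether replicate numbers pair the libraries stays open. Deviations from the group mean correlated between the oil and E2 libraries of the same number at 0.290, −0.181 and 0.383 in WT, −0.0753, 0.313 and 0.172 in KIKO and 0.00445, −0.147 and −0.164 in ERKO. The E2 library of the same number correlated highest for WT 3, KIKO 2 and KIKO 3 and not for the others, which decides nothing. Alternatives for count data were not run, since the values are FPKM. The implied depth limits genes of low FPKM.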

Other observations

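The tests in this part were chosen after the result was seen. Of the 27 genes that fell with E2 in WT, 23 were lower in KIKO oil than in WT oil and 27 in ERKO oil, and 2 and 13 of them passed the threshold. Timp1 passed in both, and Procr, Vgf and Pdyn in ERKO oil. Kiss1 was not lower in KIKO oil, at 504 FPKM against 433 FPKM in WT oil. A candidate explanation is that the genotype alone lowers some of these genes. Their median log2 difference from WT oil was −0.40 in KIKO oil, below the range of −0.148 to −0.0807 in 100 simulations with equal groups and the same shared WT oil libraries, and −0.67 in ERKO oil, below −0.140 to −0.0830, while their median change in WT was −1.14. Each gene was simulated on its own, without shifts that a library shares across genes, and with the WT changes taken as measured. The simulated range may therefore be too narrow, and it does not settle whether genotype is the cause. Genotype and any processing order cannot be told apart here either.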
